A study of Homo sapiens with 12 samples.

How the data were processed

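RNA-seq was deposited for 12 libraries from human pancreatic cancer cells of the lines Panc-1 and MIA PaCa-2, in 4 groups of 3: control and miR-29a overexpression (OE) in each line. Per the labels, cells were grown in high-glucose DMEM with 10% fetal bovine serum, RNA was extracted with Trizol, and 1 ug of RNA went into TruSeq libraries. How miR-29a was overexpressed and which RNA the control cells carried is not given in the sources used here. Per the submitters' processing notes, the tools were bcl2fastq, STAR 2.5, featureCounts of Subread 1.5.1 and edgeR 3.20.8, on genome build hg38, with no parameters stated. In the authors' mapping statistics, 97.69% to 99.59% of reads on coding sequence fell on the reverse strand.

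Each line came as a workbook of its own. The deposited gene tables hold raw counts per gene, without normalization, for 15537 genes in Panc-1 and 15252 in MIA PaCa-2. They had been filtered on low counts, since the lowest second-highest value of any gene was 0.506 CPM in Panc-1 and 0.502 CPM in MIA PaCa-2. The same deposited tables hold the authors' log2 CPM (counts scaled by library total) with a prior count, and the authors' log2 fold changes and p-values from edgeR, which served only for comparison. Per the file headers, other columns give gene length in bases and a mark of 0 or 1 for miR-29-3p targets, whose source is not stated. The deposited mapping statistics give numbers of reads per class and percentages of high-quality reads, and 88.63% to 94.01% of those reads were assigned to genes. Enrichment tables of the authors' own gene lists were not used here, since they hold no values per library.

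Total counts per library were 22429361 to 26122217 in Panc-1 and 25889071 to 28934190 in MIA PaCa-2. The spread between replicates was far above counting noise: a chi-square per degree of freedom between libraries of 1 group, which is near 1 for counting noise alone, ranged from 10.3 (MIA PaCa-2 OE replicates 1 and 4) to 232 (Panc-1 control replicates 1 and 2). Depth therefore limited mainly genes with few counts.

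Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr with its defaults (minimum count 10, minimum total 15, proportion 0.7), libraries were scaled by TMM, and groups were compared with the robust quasi-likelihood F-test. P-values were adjusted by Benjamini and Hochberg, and genes with an adjusted p under 0.05 were called. Fold changes are OE over control on the log2 scale; their standard errors are the absolute fold change divided by the square root of the F statistic. CPM values are group means with standard deviations over 3 libraries. Tables of the lines were joined by gene identifier, which gave 14244 genes in both.

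The comparisons, tests, gene lists and the rule for named genes were chosen before the data were examined. In Panc-1 the design was OE against control without a block, since no label calls it paired. In MIA PaCa-2 the replicate number was a block, since the authors' name for that workbook calls the analysis paired. The difference of the OE effect between the lines was tested as the line by OE interaction over all 12 libraries with 4 groups and no block. Shared calls were counted per direction, with a one-sided Fisher's exact test.

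Pairing by replicate number was checked on each library's deviations from its group mean across genes. Libraries with the same number correlated at 0.906, 0.857 and 0.743 in Panc-1 and at 0.434, 0.538 and 0.29 in MIA PaCa-2, all above the minimum of 0.1 set for treating them as pairs. Libraries with different numbers correlated between -0.829 and 0.578 in Panc-1 and between -0.467 and 0.184 in MIA PaCa-2, with 2 of the 6 combinations in each line above that minimum too; each library correlated best with the one of its own number. For Panc-1, for shared genes and for the interaction, values with the block are therefore printed beside those without it wherever the block changes a call or a count. For MIA PaCa-2, counts of list members are those with the block, with a few without it given as examples. For Panc-1, for shared genes and for the interaction, the rule for named genes gave none without the block, so it was applied to the blocked fits; this was chosen after the data were seen, as was the analysis without both libraries labelled Panc-1 replicate 1.

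Named genes were, in each line, the 6 largest increases and the 6 largest decreases among called genes with at least 5 CPM and the same direction in all 3 same-numbered pairs. Added were the 10 decreases and 6 increases shared by both lines with the largest smaller-of-the-pair fold change, among genes with at least 5 CPM in each line, up to 3 members of each list with the smallest p in each line, and the 4 highest and 4 lowest interaction calls with at least 5 CPM in each line. MIR29A, MIR29B1, MIR29B2, MIR29C, MIR29B2CHG, LOXL2, COL1A1, COL4A1, SPARC, DNMT3A, DNMT3B, TET3, MCL1, CDK6, TFEB, ATG9A and MYC were named whatever their values. MIR29B1, MIR29B2, MIR29C and MIR29B2CHG had no entry in either table.

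The 19 gene lists were published miR-29 targets of the matrix, other published miR-29 targets, collagen biosynthesis and crosslinking enzymes, basement membrane and laminins, DNA methylation and demethylation, autophagy and lysosome, mesenchymal markers, epithelial and ductal markers, cell cycle, MYC targets, p53 targets, BCL2 family apoptosis regulators, type I interferon response, cholesterol biosynthesis, unfolded protein and integrated stress response, hypoxia and glycolysis, markers of other cell types, mitochondrially encoded mRNAs, and replication-dependent histones. Some genes are in more than 1 list. Lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, and again with an estimated correlation, adjusted over the 19 lists. For seed sites and the authors' marked targets, camera's p is that of a single test and is not adjusted. Rotation tests (fry) were run as an alternative.

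Sites for miR-29a-3p were searched in the annotated 3' UTRs of protein-coding transcripts of GENCODE release 29 on hg38. Of 16545 genes in either table, 16491 matched that release by identifier, 13285 had a searched 3' UTR and 2827 of these had a site. Genes without a searched 3' UTR were left out of the site tests. A scan of all 7-base words related each word in the longest 3' UTR to the fold change after 3' UTR length and GC content, for words found in at least 50 genes.

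Alternatives were DESeq2 1.42.0, DESeq2's size factors, edgeR's likelihood ratio test, no filter on low counts, a minimum 2-fold change, the block added or removed, each library left out in turn, an estimated correlation, 8mer sites alone, and sites in the longest 3' UTR. A correction for GC content and length was added after the data were seen. The fits were tested on simulated data with the spread of these libraries. Of 67 genes changed 2-fold (log2 change of 1), the test recovered 58 in MIA PaCa-2 and 53 in Panc-1 with the block. It recovered 0 in Panc-1 without it. Calls among unchanged genes numbered 27, 8 and 0. The 27 in MIA PaCa-2, beside 31, 58 and 65 recovered at log2 changes of 0.5, 1 and 2, exceed the share that the adjusted p threshold aims at. At a log2 change of 0.5 the test recovered 31 of 66 genes in MIA PaCa-2 and 5 of 66 in Panc-1 with the block. A gene that did not pass in Panc-1 may thus still have changed by that much. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.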

Results

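Gene-level RNA-seq counts were analysed for 12 libraries of Panc-1 and MIA PaCa-2, established cell lines derived from human pancreatic carcinomas. Each line had 3 control libraries and 3 libraries labelled as overexpressing (OE) miR-29a, a microRNA that binds mRNAs mainly through matches to its seed in 3' untranslated regions (3' UTRs). Replicate numbers were 1, 2 and 3 in Panc-1 and 1, 2 and 4 in MIA PaCa-2. Total counts per library ranged from 22429361 to 26122217 over 15537 genes in Panc-1, and from 25889071 to 28934190 over 15252 genes in MIA PaCa-2. Per the design text of the series, control cells were set against OE cells in each line, and targets shared by both lines were followed further.

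Mature miR-29a is not counted in a gene-level mRNA table, so the overexpression itself was not checked here. The entry MIR29A (ENSG00000226380.8, chromosome 7, positions 130876747 to 130913310 in hg38) is annotated as a long intergenic RNA. It was at 4.05 ± 0.824 to 5.62 ± 1.85 CPM (SD, n = 3) from control to OE in Panc-1 and at 9.92 ± 2.33 to 14.7 ± 4.52 CPM in MIA PaCa-2. Its log2 fold change was 0.45 ± 0.23 (SE) in Panc-1 with the replicate block (adjusted p = 0.224, edgeR quasi-likelihood test, Benjamini-Hochberg) and 0.55 ± 0.12 in MIA PaCa-2 (adjusted p = 0.00594, the same test).

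The libraries labelled Panc-1 replicate 1, control and OE alike, stood apart from the other Panc-1 libraries. The first principal component of the Panc-1 log2 CPM held 75.3% of the variance and placed this pair at -109 and -104, with the other 4 libraries between 48.8 and 56.9. Across 14244 genes, the control library labelled replicate 1 correlated at 0.961 to 0.969 with the MIA PaCa-2 controls and at 0.924 to 0.934 with the other Panc-1 controls. In MIA PaCa-2 the first component held 51.7% of the variance and separated control from OE libraries. Panc-1 counts of called genes are therefore given also without this pair.

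**Figure D1:**
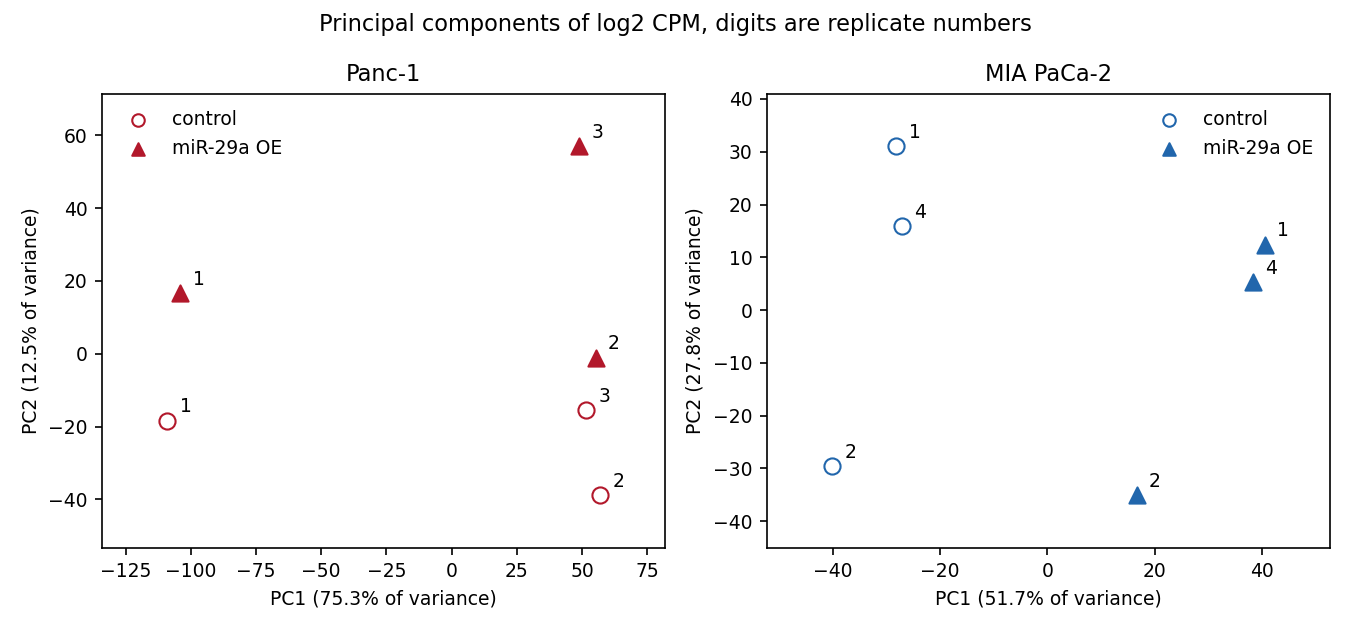
Principal components of log2 CPM, computed in each line separately, with 1 point per library (open circles for control, filled triangles for miR-29a OE, digits for replicate numbers). The libraries labelled Panc-1 replicate 1 lie at -109 and -104 on the first Panc-1 component, away from the other 4.

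In Panc-1, published matrix targets of miR-29 that passed the test, collagens among them, fell with miR-29a OE, and type I interferon response genes that passed it rose, when libraries with the same replicate number were compared within pairs. In this paired fit camera's calls for both lists were lost with an estimated correlation (adjusted p = 0.129 and 0.362). COL1A2 (ENSG00000164692.17, chromosome 7, positions 94394561 to 94431232), which encodes a chain of type I collagen, fell from 286 ± 48.9 to 45.2 ± 18.1 CPM (SD, n = 3), a log2 fold change of -2.72 ± 0.17 (SE; adjusted p = 1.51e-07, edgeR quasi-likelihood test with the replicate block, Benjamini-Hochberg). COL1A1, the other chain of type I collagen, changed by -2.22 ± 0.17, and COL4A2, a basement membrane collagen, by -2.24 ± 0.17. CLDN1 (ENSG00000163347.5, chromosome 3, positions 190305701 to 190322475), a tight junction protein, had a log2 fold change of -2.81 ± 0.22, PRMT6, an arginine methyltransferase, -2.17 ± 0.20, and FBN1, the microfibril protein fibrillin, -2.14 ± 0.24. Among genes that rose, C3orf52 went from 2.98 to 15.6 CPM (2.40 ± 0.21), the neuronal gene CEND1 changed by 2.22 ± 0.34, and S100A2, a calcium-binding protein, went from 35.9 to 151 CPM (2.19 ± 0.19). The neutrophil chemokine CXCL5 rose by 2.12 on the log2 scale (SE 0.28), the chemokine CCL5 by 1.88 (SE 0.22), and OAS1, an interferon-induced sensor of double-stranded RNA, by 1.91 (SE 0.33). All of these genes moved the same way in the 3 pairs, which the rule for naming them required.

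With the replicate block, edgeR's quasi-likelihood test called 1767 of 15282 genes in Panc-1, 781 up and 986 down, of which 271 and 224 changed at least 2-fold. Nothing in the labels says that replicates were separate cultures, so all p-values here measure the spread between these libraries. Without the block, the design fixed for this line, the same test called 0 genes. The count at an unadjusted p under 0.05 was then 811, DESeq2 called 115 and edgeR's likelihood ratio test 43. Other splits of the Panc-1 libraries without the block gave 2 to 3179 genes at that unadjusted threshold, so the 811 show no effect by themselves. Blocked calls numbered 683 without Panc-1 control replicate 2, 682 without Panc-1 miR-29a OE replicate 2, and 2444 without the pair labelled replicate 1, of which 1499 were among the 1767 with the same direction. In the authors' deposited edgeR values for Panc-1, 2517 genes had an adjusted p under 0.05, and these include all 1767. The authors' test may not be the quasi-likelihood test, since edgeR's likelihood ratio test with the block called 2492 here. The authors' fold changes correlated at 0.99985 across genes with the blocked values and at 0.991 with the unblocked ones.

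Published miR-29 targets that passed the test in Panc-1 all fell. Of the 32 measured matrix targets, 21 fell and 0 rose with the block, with a median log2 fold change of -1.11; adjusted over the list alone, 24 fell. Examples besides the collagens were LOXL2 (ENSG00000134013.15, chromosome 8, positions 23297189 to 23425328), a lysyl oxidase that crosslinks collagen, at -2.05 ± 0.18, and FSTL1, a secreted glycoprotein (-1.58 ± 0.17). SPARC, a matrix glycoprotein, did not pass the test (-0.07 ± 0.31). Of 43 measured targets outside the matrix list, 19 fell and 0 rose, and 21 fell adjusted over the list alone. They included CDK6, a G1 cyclin-dependent kinase (-1.89 ± 0.21), the 5-methylcytosine dioxygenase TET1 (-1.55 ± 0.22) and the immune checkpoint protein CD276 (-1.23 ± 0.16). MCL1, an antiapoptotic BCL2 family member, was at -0.33 ± 0.16 and not past the test, though it was without the pair labelled replicate 1 (-0.56, adjusted p = 0.0392, edgeR). TFEB, a regulator of lysosomal genes, was at -0.10 ± 0.20 and did not pass.

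Camera with its preset correlation called both target lists down in the unblocked Panc-1 fit (adjusted p = 3.69e-26 and 5.75e-10, edgeR and limma, Benjamini-Hochberg). Both calls held with an estimated correlation (adjusted p = 0.0221 for each), but not with an estimated correlation in the blocked fit (adjusted p = 0.129 and 0.362), nor with an estimated correlation without the pair labelled replicate 1 (adjusted p = 0.0854 and 0.288). Without the block, 0 members of either list passed over all genes, and 11 and 2 fell adjusted over the list alone.

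For the next lists, counts of members and fold changes are with the block, and camera's values are without it. Of 27 collagen biosynthesis and crosslinking enzymes measured in Panc-1, 9 fell and 0 rose, the same adjusted over the list alone. Among them were SERPINH1, the collagen chaperone (-1.49 ± 0.15), COLGALT1, a collagen galactosyltransferase (-1.53 ± 0.18), and P3H1, a prolyl hydroxylase (-1.31 ± 0.19). The camera call (adjusted p = 2.12e-05) was lost with an estimated correlation (adjusted p = 0.0604). Of 20 basement membrane and laminin genes, 7 fell and 1 rose, with the same 7 and 1 adjusted over the list alone. COL4A1 (-1.84 ± 0.21), the laminin-binding protein nidogen NID1 (-1.96 ± 0.19) and the proteoglycan HSPG2 (-1.05 ± 0.18) fell, and camera gave adjusted p = 0.00323 (0.363 with an estimated correlation). DNA methylation and demethylation genes had 7 members down and 1 up of 21, and 7 down and 3 up adjusted over the list alone. TET2 (-1.55 ± 0.26), TET3 (-1.28 ± 0.20) and the de novo methyltransferases DNMT3A (-0.85 ± 0.17) and DNMT3B (-1.07 ± 0.21) fell (camera adjusted p = 0.00524, and adjusted p = 0.104 with an estimated correlation). SERPINH1, COL4A1 and NID1 are also in the list of matrix targets, and TET2, TET3, DNMT3A and DNMT3B in the list of other targets. Their decreases are thus not results separate from those lists. Without the block 0 members of the lists in this paragraph passed over all genes. Adjusted over the list alone, 5 collagen enzymes, 3 basement membrane genes and 1 DNA methylation gene then fell. In the blocked fit camera with an estimated correlation gave adjusted p = 0.363, 0.362 and 0.363.

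Most type I interferon response genes rose in Panc-1. With the block 29 of 38 members rose and 0 fell, with a median log2 fold change of 1.13, and 31 rose adjusted over the list alone. ISG15, a ubiquitin-like modifier, went from 64.6 to 207 CPM (1.73 ± 0.21), the RNA sensor IFIH1 from 7.82 to 24.3 CPM (1.61 ± 0.19), OAS3 from 19.1 to 51.1 CPM (1.38 ± 0.17) and the RNA sensor DDX58 from 48.5 to 92.3 CPM (0.94 ± 0.17). The median log2(CPM + 1) ratio of the list was 0.50 in the pair labelled replicate 1, 1.12 in pair 2 and 0.77 in pair 3. Camera called the list up without the block (adjusted p = 2.09e-22), also with an estimated correlation (adjusted p = 0.0221), but not with an estimated correlation in the blocked fit (adjusted p = 0.362) or without the pair labelled replicate 1 (adjusted p = 0.0854). Without the block, 1 member rose adjusted over the list alone.

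Most mitochondrially encoded mRNAs fell in Panc-1 with the block, with 10 of 13 down and 0 up, and 11 down adjusted over the list alone. Without the block 0 passed, over all genes or adjusted over the list alone. MT-ATP6 and MT-ATP8, subunits of ATP synthase whose genes overlap, were at -0.87 ± 0.15 and -1.03 ± 0.17, and MT-CYB, cytochrome b, at -0.88 ± 0.15. Without the block camera gave adjusted p = 1.95e-07, and adjusted p = 0.363 with an estimated correlation. The mitochondrial share of reads in the authors' mapping statistics was lower in the OE library of each pair, at 0.809% in control and 0.734% in OE, 1.41% and 1.06%, and 1.16% and 0.791%.

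Of 24 mesenchymal markers measured in Panc-1, 8 fell and 0 rose with the block, and adjusted over the list alone 9 fell and 1 rose. Without the block 0 passed over all genes, and 1 fell adjusted over the list alone. TGFB2, a TGF-beta ligand (-1.97 ± 0.21), the transcription factor SNAI2 (-1.26 ± 0.23), the integrin ITGA5 (-1.0 ± 0.15) and the receptor kinase AXL (-0.81 ± 0.16) fell. Camera did not call this list without the block (adjusted p = 0.0848) and called it down with it (adjusted p = 0.00199; adjusted p = 0.485 with an estimated correlation). MYC targets went the other way: camera called them up without the block (adjusted p = 0.045, and adjusted p = 0.588 with an estimated correlation) and not with it (adjusted p = 0.0621). Of 35 MYC targets 2 rose with the block, namely the ribosome biogenesis genes RRP9 (0.80 ± 0.17) and FBL (0.54 ± 0.16), and 1 rose adjusted over the list alone. MYC itself was at -0.41 ± 0.15 and did not pass (adjusted p = 0.0913); without the pair labelled replicate 1 it was at -0.56 (adjusted p = 0.0456, edgeR).

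The remaining lists were not called by camera in Panc-1 in either fit. Their counts of members are those with the block, and without it 0 genes passed over all genes. Epithelial and ductal markers had 4 up and 1 down of 19 (4 and 2 adjusted over the list alone), with the mucin MUC1 (1.15 ± 0.17) and the keratins KRT8 (0.58 ± 0.15) and KRT18 (0.56 ± 0.15) up and the desmosomal DSP down (-0.68 ± 0.18). Cell cycle genes had 3 up and 6 down of 45, the same adjusted over the list alone, with RRM2, a ribonucleotide reductase subunit, up (0.85 ± 0.16) and the mitotic kinase PLK1 down (-0.81 ± 0.16). Without the pair labelled replicate 1, camera called the cell cycle list down (adjusted p = 0.00303 with the block; adjusted p = 0.427 with an estimated correlation) and the epithelial list up (adjusted p = 0.0309; adjusted p = 0.427 with an estimated correlation). Autophagy and lysosome genes had 3 up and 3 down of 48 (3 and 4 adjusted over the list alone), with ATG9A, an autophagy membrane protein (-0.85 ± 0.15), and ATP6AP1, a subunit of the vacuolar proton pump (-1.04 ± 0.15), down. The p53 targets had 4 up and 7 down of 29 (5 and 10 adjusted over the list alone), with the BH3-only gene PMAIP1 up (1.12 ± 0.17) and TRIAP1 down (-1.03 ± 0.16). For the autophagy and p53 lists the median was above 0 (0.03 and 0.10) while the mean (-0.04 and -0.06) and camera pointed down.

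BCL2 family regulators in Panc-1 had 1 up and 2 down of 19 with the block, the same adjusted over the list alone, with the pore-forming protein BAK1 at -0.80 ± 0.17. Their median was 0.02 and their mean -0.03 with the block. Camera pointed up with the block and down without it. Cholesterol biosynthesis genes had 1 up and 3 down of 24 (2 and 3 adjusted over the list alone), with INSIG1, a regulator of sterol synthesis, down (-0.70 ± 0.17). Unfolded protein and integrated stress response genes had 4 up and 1 down of 29, the same adjusted over the list alone, with the chaperone CANX (0.95 ± 0.15) and CHAC1 (1.06 ± 0.20) up. Hypoxia and glycolysis genes had 4 up and 1 down of 28 (4 and 2 adjusted over the list alone): the glucose transporter SLC2A3 fell (-2.03 ± 0.16) and the kinase PFKFB4 rose (0.69 ± 0.15). Camera called this list up without the pair labelled replicate 1 and without the block (adjusted p = 0.043, and adjusted p = 0.644 with an estimated correlation). Of 10 replication-dependent histone genes 0 passed edgeR's quasi-likelihood test with the block, with HIST1H2AG and HIST1H2BK, 2 of the 10, at an unadjusted p under 0.05. Only 4 of 24 markers of other cell types were tested, with 1, the endothelial cadherin CDH5, down at 2.31 CPM in controls (-1.30 ± 0.33).

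In MIA PaCa-2, collagen and mitotic cell cycle genes that passed the test mostly fell with miR-29a OE, and hypoxia, stress response and epithelial genes that passed it mostly rose, although camera's calls for the lists that hold them were lost with an estimated correlation (adjusted p from 0.116 to 0.315). COL3A1 (ENSG00000168542.13, chromosome 2, positions 188974320 to 189012746), the type III collagen chain, went from 19.9 ± 8.84 to 0.287 ± 0.0316 CPM (SD, n = 3), a log2 fold change of -6.09 ± 0.21 (SE; adjusted p = 4.34e-07, edgeR quasi-likelihood test with the replicate block, Benjamini-Hochberg). COL1A2 went from 662 ± 222 to 53.4 ± 12 CPM (-3.61 ± 0.09), COL5A2, a fibrillar collagen, from 582 to 88.6 CPM (-2.72 ± 0.08), and C1QTNF6, a secreted C1q-related protein, from 30.9 to 3.75 CPM (-3.05 ± 0.12). MYBL2, a transcription factor of cell cycle genes, had a log2 fold change of -2.87 ± 0.10, and TM4SF18, a tetraspan membrane protein, -2.79 ± 0.15. Among genes that rose, the activity-induced gene ARC went from 4.04 to 35.4 CPM (3.16 ± 0.13), FA2H, a fatty acid hydroxylase, from 1.22 to 9.86 CPM (3.02 ± 0.18), and ANKRD37, a hypoxia-induced gene, from 5.1 to 36.7 CPM (2.63 ± 0.29). Complement C3 rose by 2.52 on the log2 scale (SE 0.16), the chemokine CCL22 by 2.35 (SE 0.13) and the phosphatase PPM1J by 2.29 (SE 0.23). All of these moved the same way in the 3 pairs, which the rule for naming them required.

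The test called 5716 of 15142 genes in MIA PaCa-2, 2914 up and 2802 down, of which 423 and 541 changed at least 2-fold. Without the replicate block it called 2500 (1175 up and 1325 down). Counts of list members given below for this line are with the block, and they were lower for many lists without it. Without it 23 of 45 cell cycle genes and 13 of 27 matrix targets fell and 0 rose, and 4 of 27 hypoxia and glycolysis genes rose and 1 fell. Of the genes named here, MIR29A, COL1A1, BCL2L11, BAX, RRM2, HK2, PFKFB4, FDFT1, DHCR7 and MAP1LC3B were then not past the test, with adjusted p between 0.0604 and 0.347. The count was 3242 without MIA PaCa-2 control replicate 4 and 3330 without MIA PaCa-2 miR-29a OE replicate 4. In the authors' deposited edgeR values for this line 5768 genes had an adjusted p under 0.05, of which 5711 were among the 5716.

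Matrix targets of miR-29 fell in MIA PaCa-2 for 20 of 27 measured members, while 2 rose, and the counts were the same adjusted over the list alone. The median log2 fold change was -1.03. LOXL2 fell (-2.42 ± 0.09), COL4A2 changed by -2.05 ± 0.10 and COL4A1 by -1.46 ± 0.11, while COL1A1 was low in this line (3.4 to 1.58 CPM; -1.03 ± 0.25). Camera called the list down (adjusted p = 2.2e-28, edgeR and limma, Benjamini-Hochberg), a call lost with an estimated correlation (adjusted p = 0.116) but not with one in the fit without the block (adjusted p = 0.00742). Targets outside the matrix list had 17 down and 8 up of 44 (17 and 9 adjusted over the list alone), with camera adjusted p = 0.0444 and adjusted p = 0.308 with an estimated correlation. CD276 (-1.19 ± 0.11), the secretase BACE1 (-1.12 ± 0.10) and the GTPase CDC42 (-0.81 ± 0.08) fell, and the BH3-only gene BCL2L11 rose (0.78 ± 0.08). MCL1 was at 0.02 ± 0.08 and TFEB at -0.32 ± 0.21, neither past the test.

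Collagen biosynthesis and crosslinking enzymes had 11 down and 4 up of 24 in MIA PaCa-2, the same adjusted over the list alone, led by SERPINH1 (-1.68 ± 0.08), COLGALT1 (-1.61 ± 0.09) and P3H1 (-1.60 ± 0.09); camera adjusted p = 1.49e-08, and adjusted p = 0.315 with an estimated correlation. DNA methylation genes had 10 down and 2 up of 21, the same adjusted over the list alone, with TET3 (-0.82 ± 0.09), TET2 (-0.89 ± 0.12) and MBD3 (-0.77 ± 0.09) down. For this list camera gave adjusted p = 0.00409, and adjusted p = 0.308 with an estimated correlation. DNMT3A fell (-0.66 ± 0.11), and DNMT3B, at -0.31 ± 0.14, did not pass. SERPINH1 is also in the list of matrix targets, and TET2, TET3, DNMT3A and DNMT3B are in that of other targets. The basement membrane list had 4 down and 3 up of 17, the same adjusted over the list alone, and was not called (camera adjusted p = 0.0736); the laminin chain LAMB3 rose (1.12 ± 0.12).

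Cell cycle genes fell in MIA PaCa-2 for 38 of 45 members, with 2 up, the same adjusted over the list alone. The mitotic kinase PLK1 went from 103 to 39.2 CPM (-1.40 ± 0.09), the kinesin KIF20A from 90.1 to 38.6 CPM (-1.22 ± 0.09) and BIRC5, a chromosomal passenger protein, from 119 to 54 CPM (-1.16 ± 0.09), while RRM2 rose (0.66 ± 0.15). The list's median was -0.57, and camera gave adjusted p = 3.48e-16 (adjusted p = 0.315 with an estimated correlation). MYC targets had 14 up and 2 down of 35, the same adjusted over the list alone, with RRP9 (0.92 ± 0.10), FBL (0.61 ± 0.10) and hexokinase HK2 (0.77 ± 0.08) up; camera adjusted p = 0.0183, and adjusted p = 0.308 with an estimated correlation.

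Members of stress and metabolic lists that passed the test mostly rose in MIA PaCa-2. Unfolded protein and integrated stress response genes had 14 up and 3 down of 29 (16 and 3 adjusted over the list alone), with the stress-induced factors ATF3 (37.8 to 156 CPM; 2.03 ± 0.09) and DDIT3 (0.88 ± 0.10) and the chaperone CANX (1.16 ± 0.08) up; camera adjusted p = 1.12e-05, and adjusted p = 0.308 with an estimated correlation. Hypoxia and glycolysis genes had 15 up and 2 down of 27 (17 and 3 adjusted over the list alone), with HK2 and PFKFB4 (0.91 ± 0.10) up and the mutase PGAM1 down (-0.77 ± 0.08); camera adjusted p = 1.6e-05, and adjusted p = 0.308 with an estimated correlation. Cholesterol biosynthesis genes had 11 up and 3 down of 23, the same adjusted over the list alone, including the enzymes MSMO1 (1.05 ± 0.16), FDFT1 (0.68 ± 0.08) and DHCR7 (0.66 ± 0.08). That call (camera adjusted p = 0.0261) was lost with an estimated correlation (adjusted p = 0.399) and without the block (adjusted p = 0.0801). Epithelial and ductal markers had 6 up and 0 down of 14 (7 adjusted over the list alone), with MUC1 (1.48 ± 0.09), KRT19 (0.81 ± 0.08) and KRT18 (0.66 ± 0.09) up; camera adjusted p = 0.000809, and adjusted p = 0.308 with an estimated correlation.

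Camera called no other list in MIA PaCa-2. Interferon response genes had 8 up and 7 down of 36, the same adjusted over the list alone, with a median of -0.01 and a mean of 0.03, and camera pointed up. ISG15 rose (0.62 ± 0.11) and IFIT1, an RNA-binding antiviral protein, fell (-0.53 ± 0.10). Autophagy and lysosome genes had 11 up and 11 down of 48 (11 and 12 adjusted over the list alone), with the autophagosome protein MAP1LC3B up (0.68 ± 0.08) and ATP6AP1 (-1.22 ± 0.09) and ATG9A (-0.69 ± 0.09) down. Mesenchymal markers had 5 up and 3 down of 14 (5 and 4 adjusted over the list alone), with ITGA5 down (-0.83 ± 0.11). The p53 targets had 7 up and 8 down of 28 (9 and 9 adjusted over the list alone), with the cyclin-dependent kinase inhibitor CDKN1A up (1.39 ± 0.10); their median was -0.03 and their mean 0.03, and camera pointed up. BCL2 family regulators had 6 up and 1 down of 18, the same adjusted over the list alone, with BBC3 up (0.81 ± 0.11) and BAX down (-0.57 ± 0.09). Mitochondrially encoded mRNAs had 5 down and 1 up of 13, the same adjusted over the list alone. Histones had 2 down and 1 up of 9, and 5 of 24 markers of other cell types were tested, with 2 down and 1 up, or 2 and 2 adjusted over the list alone; their median was 0.33 and their mean 0.09, and camera pointed down.

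**Figure D2:**
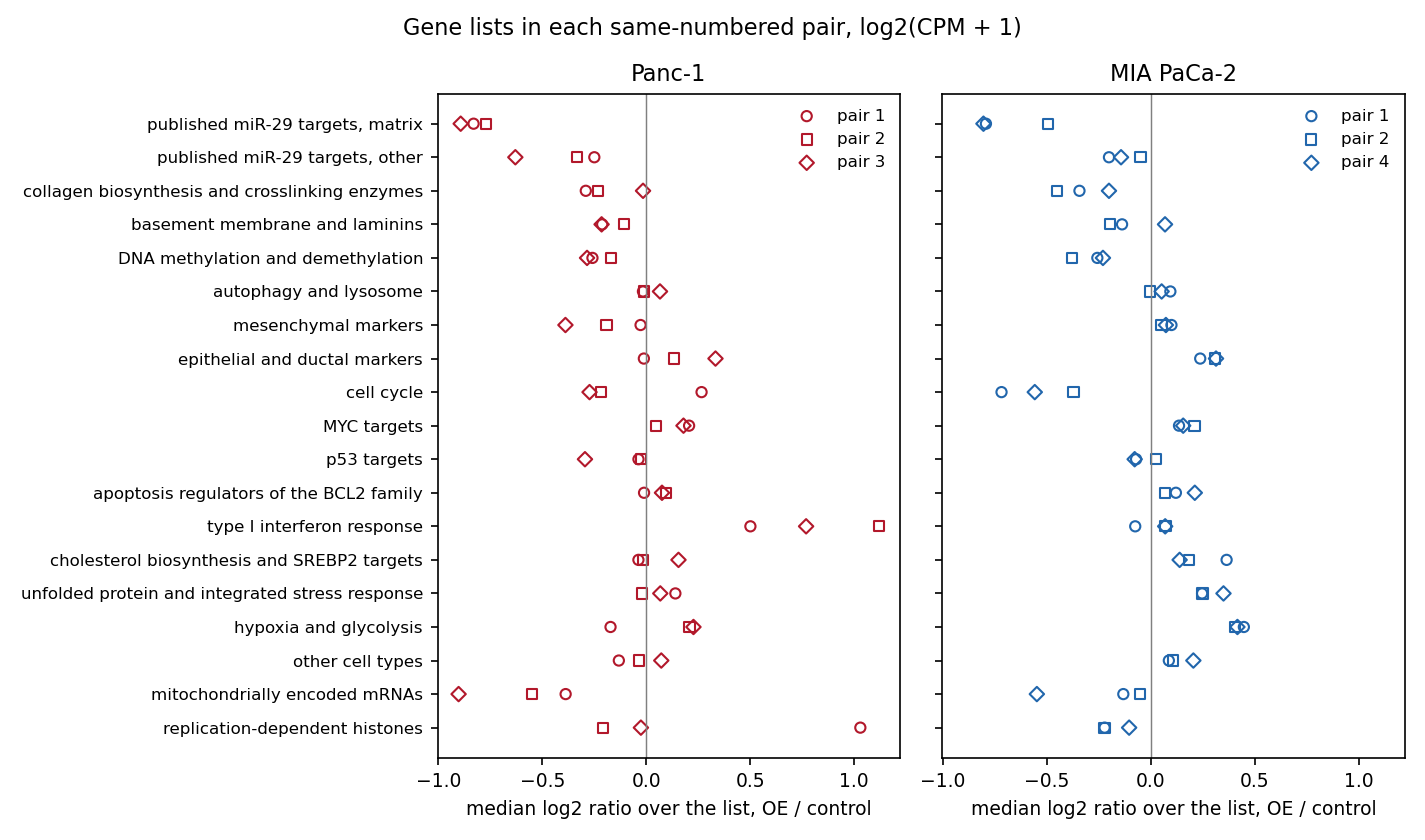
Median log2(CPM + 1) ratio of OE to control over the members of each gene list, with 1 point for each pair of libraries with the same replicate number, in Panc-1 (left) and MIA PaCa-2 (right). The matrix targets of miR-29 lie between -0.89 and -0.50 in all 6 pairs, and the interferon list lies at 0.50, 1.12 and 0.77 in Panc-1 and between -0.08 and 0.07 in MIA PaCa-2.

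Genes with a miR-29a-3p seed site in a 3' UTR had lower fold changes than genes without one, in both lines. The seed at positions 2 to 8 reads AGCACCA, and the sites searched in GENCODE v29 3' UTRs were TGGTGCTA (8mer) and its 7-base forms TGGTGCT and GGTGCTA. In Panc-1 the median log2 fold change without the block was -0.20 over 2748 genes with a site and 0.04 over 10064 without, a difference of -0.24 (camera p = 1.48e-11 on the edgeR fit; p = 0.00671 with an estimated correlation, and p = 0.0849 with one in the blocked fit). With the block, 19.0% of genes with a site fell against 4.0% of the others, an odds ratio of 5.62 (95% confidence interval 4.89 to 6.47, two-sided Fisher's exact p = 4.71e-130), and 2.87% against 6.39% rose (odds ratio 0.434). Without the pair labelled replicate 1, 23.4% against 5.6% fell. In MIA PaCa-2 the difference of medians was -0.14 (camera p = 0.000299, and p = 0.0381 with an estimated correlation), and 27.8% of 2658 genes with a site fell against 16.6% of 9755 (odds ratio 1.93, interval 1.75 to 2.14, two-sided Fisher's exact p = 2.09e-36). Without the block, 16% of genes with a site fell in MIA PaCa-2 against 7.3% of the others. Sites were found in 56.4% of searched Panc-1 genes called down with the block and in 31.3% of those in MIA PaCa-2. Genes are not independent replicates, so these tests describe the set of genes measured in these libraries.

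**Figure D3:**
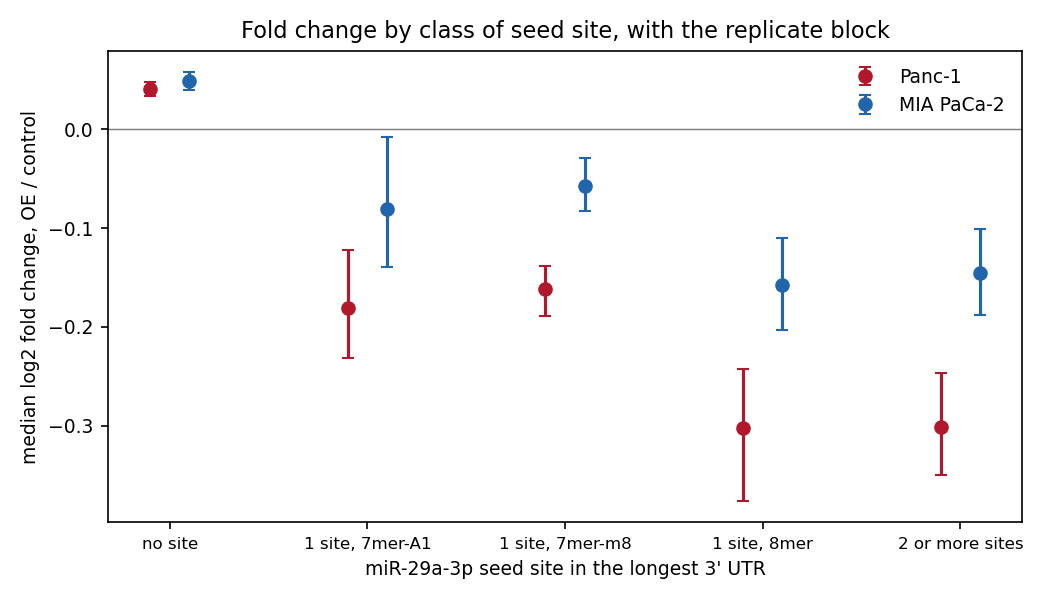
Median log2 fold change of OE against control by class of miR-29a-3p site in the longest 3' UTR, in the fits with the replicate block, with bars for the 95% bootstrap interval over genes. In Panc-1 the median was 0.04 for genes with no site, -0.18 and -0.16 with a single 7-base site, and -0.30 with a single 8mer or with 2 or more sites.

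Genes that the authors mark as miR-29-3p targets had lower fold changes than other genes in both lines. The median difference from other genes was -0.44 in Panc-1 over 1024 marked genes (camera p = 4.01e-27 on the edgeR fit; p = 0.00697 with an estimated correlation, and p = 0.0804 with one in the blocked fit). With the block, 32.3% of marked genes fell against 4.59% of the rest (odds ratio 9.92, interval 8.48 to 11.6, two-sided Fisher's exact p = 5.98e-156). In MIA PaCa-2 the difference was -0.21 (camera p = 1.94e-08, and p = 0.0302 with an estimated correlation), and 35.4% of 990 marked genes fell against 17.3% (odds ratio 2.61, interval 2.27 to 3.0). Without the block, 21.1% of marked genes fell in MIA PaCa-2 against 7.89% of the rest. A seed site was found here in 1017 of the 1054 marked genes with a searched 3' UTR.

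The genes that changed in both lines were largely changed in the same direction, when the replicate block was used in both. Collagens were among the largest shared decreases of genes with at least 5 CPM in each line: COL1A2, COL5A2 (-2.05 ± 0.17 in Panc-1), COL4A2 and the crosslinking enzyme LOXL2 fell in each line. Other shared decreases were C1QTNF6 (-2.06 ± 0.19 in Panc-1), MYBL2 (-1.99 ± 0.15 in Panc-1), PRMT6 (-2.44 ± 0.15 in MIA PaCa-2), the peptidase BLMH (-1.72 ± 0.16 and -1.81 ± 0.15), CLDN1 (-1.67 ± 0.15 in MIA PaCa-2) and the semaphorin SEMA3C (-1.84 ± 0.22 and -2.0 ± 0.12). Of these 10 genes, SEMA3C had no seed site in a searched 3' UTR. Among genes with at least 5 CPM in each line, the largest shared increases were those of C3orf52 (2.01 ± 0.15 in MIA PaCa-2), SPOCD1 (1.77 ± 0.23 and 1.84 ± 0.13), the actin-bundling protein MISP (1.75 ± 0.21 and 1.79 ± 0.09), CXCL5 (1.60 ± 0.12 in MIA PaCa-2), the neuropeptide precursor VGF (1.51 ± 0.20 and 1.56 ± 0.10) and MRPS35, a mitochondrial ribosomal protein (1.45 ± 0.16 and 1.68 ± 0.09).

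Of 14104 genes tested in both lines, 636 fell in both, against 182 for independent lists (odds ratio 10.9, one-sided Fisher's exact p = 2.14e-249), and 526 rose in both, against 147 (odds ratio 12.1, one-sided Fisher's exact p = 2.31e-214). Another 22 were called in opposite directions, a count that moved to 65 and 61 without the Panc-1 control and OE libraries labelled replicate 1, 65 without that pair, 4 without either library of Panc-1 replicate 2, 10 and 11 without MIA PaCa-2 control and OE replicate 1, 45 and 47 without those of replicate 2, and 9 and 10 without those of replicate 4. A seed site was found in 334 of the 636 and in 62 of the 526. With Panc-1 unblocked, the design fixed for this comparison, 0 genes were shared by edgeR's quasi-likelihood test, since Panc-1 had 0 calls and 811 genes at an unadjusted p under 0.05; DESeq2 shared 110 and the likelihood ratio test 41. The blocked total of 1162 became 500 without Panc-1 control replicate 2, 497 without Panc-1 miR-29a OE replicate 2, and 1255 without the pair labelled replicate 1. Shared calls made up 71.3% of the genes called up in Panc-1 and 67.2% of those called down, and 60.2% and 52% without that pair. Fold changes with the block correlated at 0.57 (Pearson) and 0.524 (Spearman) across genes, which are not independent replicates.

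**Figure D4:**
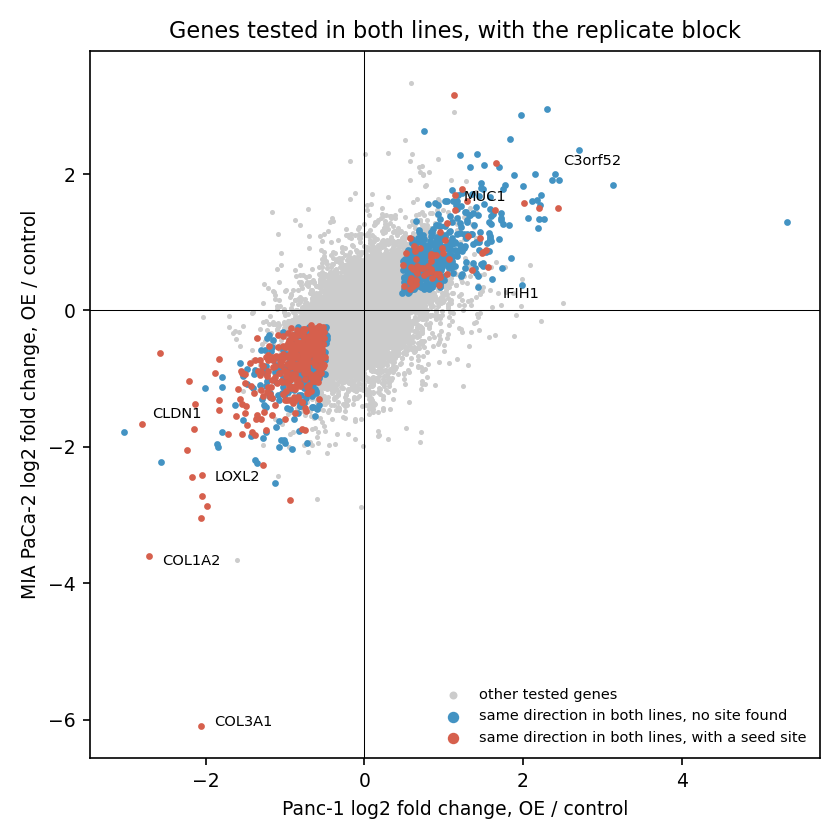
Log2 fold change of OE against control in Panc-1 (horizontal) and MIA PaCa-2 (vertical) for the 14104 genes tested in both, in the fits with the replicate block. Coloured points are the 636 genes that fell in both and the 526 that rose in both, in red where a miR-29a-3p seed site was found and in blue where none was found or no 3' UTR was searched.

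By the test of the difference itself, the effect of OE differed between the lines for interferon response genes, and for cell cycle genes at camera's preset correlation but not with an estimated one (adjusted p = 0.107). All 35 interferon genes tested in both lines had a higher fold change in Panc-1 (camera on the unblocked interaction, adjusted p = 1.44e-20, edgeR and limma, Benjamini-Hochberg; adjusted p = 0.00684 with an estimated correlation and adjusted p = 0.275 with an estimated correlation in the blocked fit). With the block, 13 of them passed over all genes, among them OAS2 (difference 2.02 ± 0.35), OAS1 (2.0 ± 0.45) and IFIT3 (1.98 ± 0.36). For the cell cycle list 42 of 45 genes were higher in Panc-1 (adjusted p = 1.43e-17), and its median ratio was 0.27 in the Panc-1 pair labelled replicate 1 against -0.22 and -0.27 in the others. Without that pair the cell cycle call was at adjusted p = 3.98e-06, and adjusted p = 0.339 with an estimated correlation. Genes with a more negative change in Panc-1 included SLC2A3, which fell there (274 to 68.2 CPM) and did not pass in MIA PaCa-2 (-0.09 ± 0.11; difference -1.92 ± 0.19). The immediate early genes FOS and DUSP1 rose in MIA PaCa-2 (1.48 ± 0.17 and 1.12 ± 0.14); FOS fell in Panc-1 (-0.71 ± 0.18), with a similar fold that did not pass without the pair labelled replicate 1 (-0.585, adjusted p = 0.203, edgeR), and DUSP1 did not pass there (-0.52 ± 0.20).

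Targets of miR-29 outside the matrix list were more negative in Panc-1 (10 of 43 differences above 0, camera adjusted p = 5.3e-05; adjusted p = 0.00684 with an estimated correlation, and adjusted p = 0.275 with one in the blocked fit). Genes with a miR-29a-3p seed site were more negative in Panc-1 too (camera p = 0.00623, 0.0462 with an estimated correlation and 0.231 with one in the blocked fit). So were genes the authors mark as targets (camera p = 2.08e-06, 0.0466 and 0.168). These tests do not account for 3' UTR GC content, 3' UTR length and gene length. Those explained 12% of the variance of fold changes in Panc-1 and 1.23% in MIA PaCa-2. After 3' UTR length and GC content, genes with the word TGGTGCT differed from others by -0.242 in Panc-1 and -0.184 in MIA PaCa-2. That gap between the lines was not tested. Calls for mesenchymal markers (adjusted p = 0.0236), stress response (0.00389), hypoxia and glycolysis (0.00366) and mitochondrial mRNAs (0.00135), each more negative in Panc-1, were lost with an estimated correlation (adjusted p = 0.166, 0.0724, 0.492 and 0.492). Without the Panc-1 pair labelled replicate 1, the hypoxia and glycolysis call was lost in the unblocked fit (adjusted p = 0.319). The matrix targets did not pass the test of the difference (adjusted p = 0.611), and the other 11 lists did not either.

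Over all 14244 genes in both tables, the unblocked interaction test, the design fixed here, called 0 genes by edgeR's quasi-likelihood test, with 470 at an unadjusted p under 0.05, 4 by DESeq2 and 1 by the likelihood ratio test. Those 470 are fewer than the share of 0.05 that chance alone would give. With the block within each line the quasi-likelihood test called 232, of which 150 were higher in Panc-1 and 82 lower. That count depended on single libraries: it was 417 and 449 without the Panc-1 control and OE libraries labelled replicate 1, 9 and 7 without those of Panc-1 replicate 2, 3 and 2 without MIA PaCa-2 control and OE replicate 1, 103 and 112 without those of replicate 2, and 25 and 25 without those of replicate 4. Without both libraries labelled Panc-1 replicate 1 it was 455. Cell line and deposited table coincide, so the level of a gene is not tested between the lines, and each effect is taken within a line. Levels of both lines do enter the checks of the interferon genes and of the libraries labelled Panc-1 replicate 1 below.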

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

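The libraries labelled Panc-1 replicate 1 were left out, and interferon fold changes and control levels were taken from separate libraries, and single genes were named from the blocked fit, only after the results were seen; the other tests in this part were planned.

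The effect of miR-29a OE differed between the lines for 7 gene lists by the interaction test of camera with its preset correlation. The median difference of log2 fold change, Panc-1 minus MIA PaCa-2, was 1.09 for the type I interferon response and 0.54 for the cell cycle. It was -0.24 for miR-29 targets outside the matrix list, -0.22 for mesenchymal markers, -0.18 for the unfolded protein and integrated stress response, -0.23 for hypoxia and glycolysis, and -0.42 for mitochondrially encoded mRNAs. With an estimated correlation, the calls for the interferon response and for the targets outside the matrix list held (adjusted p = 0.00684 for each) and those for the cell cycle (0.107), mesenchymal (0.166), stress response (0.0724), hypoxia (0.492) and mitochondrial (0.492) lists were lost, and with one in the blocked fit all 7 were lost (adjusted p from 0.275 to 0.409). At the preset correlation, the hypoxia call was also lost without the pair labelled Panc-1 replicate 1 in the unblocked fit (adjusted p = 0.319).

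With the replicate block, single genes passed the test of the difference as well. Among those with at least 5 CPM in each line, the highest differences were those of OAS2 (2.02), OAS1 (1.995) and IFIT3 (1.98), which belong to the interferon response and rose in Panc-1, and TM4SF18 (1.87), which fell more in MIA PaCa-2. The lowest were those of FOS (-2.19), SLC2A3 (-1.92), FAM46C (-1.62), a gene for a poly(A) polymerase, and DUSP1 (-1.61). Genes below that limit passed with differences beyond some of these, among them COL3A1 at 4.07 (1.74 CPM over the Panc-1 libraries), which fell in both lines and more in MIA PaCa-2, and ARC at -1.98 (2.8 CPM in Panc-1), which rose more in MIA PaCa-2.

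Of the 100 splits of the libraries drawn for the difference between the lines, 2 gave at least the 232 calls of the blocked fit, the real one included, and the highest other gave 2375. That other split kept the real labels in MIA PaCa-2 and scrambled those in Panc-1. The 12 splits of this kind gave up to 2375 calls, which points to the effect of OE in MIA PaCa-2 itself, and the 81 splits that kept neither line's labels gave 0. Splits that scramble both lines also remove the effect the lines share, so they are no measure of chance for a difference between them. Without the block the real split gave 0 calls, so all 100 splits gave as many, and the highest other gave 1896. Chance is thus excluded for neither count, and the blocked one fell to 9 and 7 without Panc-1 control and OE replicate 2, to 3 and 2 without MIA PaCa-2 control and OE replicate 1, and to 25 without MIA PaCa-2 control or OE replicate 4.

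Interferon genes rose in Panc-1 and not as a group in MIA PaCa-2. The libraries labelled Panc-1 replicate 1 are excluded as the cause, since the list's median rise with the block was 1.28 without that pair. A higher control level in MIA PaCa-2 may play a part: the list's median control level was 29.7 to 30.7 CPM there and 9.79 to 11.2 CPM in Panc-1, and the excess of the control level went with the excess of the rise across the 35 genes (Spearman rho 0.504, permutation p = 0.00226). The permutation treats the genes as independent replicates, which they are not, and cell line and deposited table coincide. The same control libraries also enter both sides of that relation. With control levels and rises taken from separate libraries the rho was 0.0725, 0.461 and 0.517. This explanation and a difference between the lines themselves, which was not tested, therefore cannot be told apart.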

How the results depend on the processing

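The GC content and length correction, the block for seed sites and marked targets, an estimated correlation for seed sites, and leaving out the pair labelled Panc-1 replicate 1 were chosen after the results were seen; the other alternatives were planned.

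The count of 5716 in MIA PaCa-2 stayed within 1.5 times under DESeq2, its size factors, the likelihood ratio test, no filter and the GC correction (4813 to 6706), and so did the blocked Panc-1 count of 1767 under the first 4 of these (1738 to 2492). The difference of medians for seed sites and for marked targets kept its sign and its preset camera call in both lines under each alternative run. The block changed the call of no gene list other than those given beside the results.

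For Panc-1 without the block, where 0 genes were called, DESeq2 called 115, the likelihood ratio test 43 and the fit with the block 1767, and 1 gene was called without the pair labelled replicate 1. The 0 shared genes became 110 with DESeq2, 41 with the likelihood ratio test, 1162 with the block in both lines and 1 without the pair. The 0 calls for the difference between the lines became 4, 1, 232 with the block in each line and 3 without the pair. With each library left out in turn, all 3 counts stayed at 0. A test on simulated changes recovered 0 of 67 genes changed by 2 on the log2 scale in Panc-1 without the block and 65 with it, so the lack of a block alone leaves such changes uncalled at this spread.

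With the block, removal of it brought the counts for Panc-1, for shared genes and for the difference between the lines to 0, and that for MIA PaCa-2 to 2500. A minimum 2-fold change, which keeps fewer genes by construction, left 495 calls in Panc-1, 964 in MIA PaCa-2, 199 shared and 139 for the difference. DESeq2 raised the blocked count for the difference to 688 and the likelihood ratio test to 997; the cause was not tested. The GC correction raised the blocked Panc-1 count to 2821, which held 1695 of the 1767 with the same direction, and shared genes to 1842; the cause was not tested. Without the pair labelled replicate 1 the blocked difference gave 455 calls; the cause was not tested.

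Leaving out each library in turn gave 682 to 2406 blocked calls in Panc-1, 3242 to 8050 in MIA PaCa-2, 497 to 1318 shared genes and 2 to 449 for the difference. In a blocked fit the partner of a library left out is absorbed by its own block, so these fits rest on pairs of the other numbers, and in a single line they have 1 residual degree of freedom, with the spread borrowed across genes. The 18 gene list calls became 3 with an estimated correlation and 17 with fry. A correlation above the preset 0.01 is not the cause for every list. In MIA PaCa-2 with the block the estimate was -0.0121 for the matrix targets and -0.0332 for hypoxia and glycolysis, whose calls were lost all the same. It was 0.369 for the cell cycle and 0.321 for the collagen enzymes. The cause was otherwise not tested.

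No named gene that was called in the reported fit or in the alternative reversed direction between them. Changes of sign in genes called in neither fit were not counted as reversals. Of 133 named genes in the blocked Panc-1 fit, 129 kept their side of the threshold with DESeq2 and 123 without the pair labelled replicate 1, where 4 lost and 6 gained a call. The 100 that were called were all lost without the block. In MIA PaCa-2, 130 of 131 kept their side with DESeq2 and 103 without the block. With each library left out in turn, 685 of 798 values in Panc-1 and 743 of 786 in MIA PaCa-2 kept their side. The 8 genes named for the difference between the lines kept it with DESeq2 and without the pair labelled replicate 1, in 51 of 96 fits with a library left out, and not without the block.

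The 6 libraries of a line make 10 splits, too few for a share under 0.05. The real split gave 0 calls in Panc-1 without the block (highest other 0, so 10 of 10 gave as many), 1767 with it (highest other 0, 1 of 10) and 5716 in MIA PaCa-2 (highest other 0, 1 of 10). Among splits that part all 3 pairs the highest other was 0 as well, and the remaining splits part 1 pair. For shared genes, 1 of 100 splits, the real one, gave as many as 1162 with the block, with 0 as the highest other. Since the other splits gave 0 calls in each line, they could share none, so this adds no test to the splits of each line. Without the block in Panc-1 all 100 gave 0, with 0 as the highest other. Chance is thus excluded for neither count.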

Other observations

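The tests on the libraries labelled Panc-1 replicate 1, on the sites of other abundant microRNAs, on single pairs and called genes for 7-base words and with the GC correction were chosen after the results were seen; the scan of 7-base words, the share of variance and the passenger strand test were planned.

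The sites of the miR-29a-3p seed were the 7-base words with the most negative association with fold change in both lines, out of 16248 scanned. TGGTGCT had a z of -22.0 in Panc-1 and -14.0 in MIA PaCa-2, and GGTGCTA -16.3 and -11.1. At the other end, GGTTGTG (13.7 and 7.57), GTTGTGA (9.90 and 6.32) and TGGTTGT (9.28 and 6.85) went with higher fold changes. In each of the 6 same-numbered pairs these 3 words had a z between 5.76 and 14.95. Fold changes of the Panc-1 pairs labelled 1, 2 and 3 correlated with the mean MIA PaCa-2 fold changes at 0.548, 0.586 and 0.435 across 10810 genes, which are not independent replicates.

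Genes rose in both lines, 526 of them with the block. For GC content or length bias, the planned test did not decide, since it asked for a low share of variance in both lines to exclude this cause. Together, 3' UTR GC content, 3' UTR length and gene length explained 12% of the variance of fold changes in Panc-1 and 1.23% in MIA PaCa-2. A correction library by library, for transcript GC content and gene length, left 856 genes up in both, against 301 for independent lists. Trends with these 2 measures, as corrected, are thus excluded as the whole cause. The 3' UTR measures were not part of that correction. A seed match of an RNA in the control cells is a candidate explanation for part of the increases, since 3 words had a z over 5 in both lines where a lack of such an RNA predicted 0. Of the 500 searched genes that rose in both, 28.6% have GGTTGTG or GTTGTGA, and of all searched genes tested in both lines 2143 have either word and 9897 have neither; the words were picked from these fold changes, so this is no separate test. The overlapping words spell a site for an RNA with CACAACC at its positions 2 to 8, and the control RNA is not named in the labels. Displacement of the cells' own microRNAs by miR-29a stays open, with a median z over the sites of 20 abundant microRNAs of -0.38 in Panc-1 and 1.41 in MIA PaCa-2, and so does an indirect effect of miR-29a, which was not tested.

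The libraries labelled Panc-1 replicate 1 stand apart from the other Panc-1 libraries. Positions were taken on a scale from 0 at the other Panc-1 controls to 1 at the MIA PaCa-2 controls. The control library labelled replicate 1 lay at 0.917 over 115 genes at least 8-fold lower in MIA PaCa-2. It lay at 0.491 over 36 genes at least 8-fold higher there, a difference of 0.426 (95% bootstrap interval 0.262 to 0.622). Panc-1 RNA in a mixture would keep the first value at or below the second. A mixture of RNA like that of these controls is thus excluded as the whole cause. RNA of the MIA PaCa-2 kind alone would not give 0.491 either. A mixture together with a further difference that lowers that value is therefore not excluded. Cells or RNA of the MIA PaCa-2 kind may account for the median position of 0.887 over all these genes (0.827 for the OE library), but not for the position of 0.491 or for MMP1, at 1750 CPM against 294 and 236 CPM in the other Panc-1 controls and 18.2 CPM in MIA PaCa-2, so the labels and counts leave this open. Other values go with it: the 141 genes with at least 10 CPM in the other Panc-1 controls that are not in the MIA PaCa-2 table were at a median of 2.73% of their level in the control library labelled replicate 1, and 3 genes were over 4-fold above both groups of controls there (16 were below both). Some go the other way. The interferon list's median in that library was 11.2 CPM, against 9.79 and 10.9 CPM in the other Panc-1 controls and 29.7 to 30.7 CPM in MIA PaCa-2 controls. The cell cycle list's median log2 ratio of OE to control was 0.27 in that pair and -0.72 to -0.37 in the MIA PaCa-2 pairs. GC content or length bias is excluded as the whole cause: with each library's trend with GC content and length removed, which took away 3.05% of the variance of the log2 ratio to the other controls, the position was 0.875 (95% bootstrap interval 0.846 to 0.909), and 0.807 in the OE library (0.766 to 0.863). No biological explanation was tested, since the labels give these libraries no group of their own, and they do not say which libraries are typical of Panc-1.

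A seed match of miR-29a-5p, the passenger strand, is excluded as a source of lower fold changes at its site AAATCAG, which had a z of 1.09 in Panc-1 and 1.37 in MIA PaCa-2.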
